A study of Homo sapiens with 9 samples.

How the data were processed

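RNA was measured on Illumina Human HT-12 bead arrays in human airway stem cells from the bronchus at passages P2, P8 and P14, with 3 arrays per passage and 9 arrays in all. The deposited values are linear intensity values that the authors had scaled, without naming the method: the mean over the 45660 probes was 362 on every array, while the medians ran from 92.6 to 112. No background had been subtracted, and the arrays had not been quantile-normalized. The raw report had been made with GSGX 1.9.0 per the file headers, and only its probe annotation was used. The raw tables hold 90 per-sample columns in total whose names match no sample label, 72 over the 12 arrays of a report and 18 over the 9 arrays of a further table, so these columns were left unused.

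The plan made before the data were examined was limma's neqc, which needs negative control probes or detection p-values. Neither could be matched to the samples. The values were instead corrected with the normexp model (saddle point estimate), raised by an offset of 16, quantile-normalized between arrays and put on the log2 scale. The offset draws fold changes of dim genes toward 0. The peak of dim probes on each array stood in for the negative controls, and a probe was above background when it exceeded the mode of that peak by 1.645 SDs. A probe was kept when it was above background on at least 3 arrays, which left 20483 probes. The filter used the arrays of all passages, so it was independent of the passage labels except through genes seen at 1 passage.

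Probe names were brought up to date with a table of RefSeq genes. Gene numbers named 34478 probes, accessions 82 and symbols 74, the symbol in the file was kept for 7916, and 3110 had no symbol. A further 312 probes were left out because their genes can show a person's sex or genotype. Each gene was read by its probe with the highest mean over the 9 arrays, which left 15728 genes. No positions are given because the build behind the array annotation is not named.

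All 9 arrays were fitted together with passage as a factor in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8). The moderated test was two-sided with an intensity trend, 6 residual degrees of freedom and a median of 11.1 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 15728 genes, and an adjusted p under 0.05 counted as passing. The comparisons were P14 against P2, P8 against P2, P14 against P8, and the change from P8 to P14 minus the change from P2 to P8. In the text a gene rose or fell if it passed this test.

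The 34 gene lists were fixed from general knowledge before the data were examined, among them oncogenes and tumour suppressors, since the authors' own lists are not in the labels. Each list was tested against all other genes with camera at a preset correlation of 0.01 and again with the estimated correlation, with Benjamini-Hochberg over the 34 lists within a comparison. A list needed at least 5 tested members. Several lists share members, such as 13 genes in both the DNA repair and the tumour suppressor list, 6 in both the NF-kB and the senescence list, and 5 in both the immediate early and the oncogene list.

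The genes named were set by a rule made before the data were examined. It took the 10 largest rises and 10 largest falls of P14 against P2, the 5 largest each way of the other comparisons, and up to 4 passing members of each list with the largest change in P14 against P2. For oncogenes and tumour suppressors it took up to 6 each way. It also took 25 genes always, and 2 members of a list in which none passed. Rises and falls of the pairwise comparisons had to have all 3 arrays of 1 passage above all 3 of the other. S100A4, COL1A1 and the further fibroblast genes of the closing section stand outside this rule, and some genes that the rule names are not reported here.

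The procedure was tested on simulated data, with 200 changed genes in each of 10 runs. Of the changed genes that passed the filter in the simulated data, it recovered 52.8% of 606 changes of 0.5 on the log2 scale. For changes of 1 and 2 it recovered 70.5% of 596 and 86.4% of 602. Changed genes that the filter removed are not counted, so recovery over all changed genes was lower. The mean estimates were 0.37, 0.69 and 1.39, so the changes of genes drawn at random were on average estimated too small. Most genes named here were picked by the size of their change, so this average does not carry over to them. Of all calls in the simulated comparison, 7.49% were false. The simulation changed few genes, with rises and falls equally likely and with noise independent between genes. In the real comparison of P14 against P2 27.7% of genes passed, so these rates do not carry over to it.

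The alternatives were log2 values without background correction, median scaling, cyclic loess, an offset of 50, no filter, a stricter filter at 2.326 SDs on all 9 arrays, the mean over a gene's probes, the deposited values on the log2 scale, replicate number as a term, array weights, no intensity trend, a fit on only the passages compared, and leaving out each array in turn. For these arrays, depth is limited by signal over background and by their number. The labels do not say whether the 3 arrays of a passage came from separate cultures, so errors and p-values describe the spread between these arrays, which may be technical only.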

Results

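Gene expression was profiled in human airway stem cells, the cells of the bronchus that renew its lining, during serial passage in a medium that blocks SMAD signalling. The medium held inhibitors of the TGF-beta and BMP receptors, a ROCK inhibitor and an inhibitor of GSK3. Cells were collected at P2, P8 and P14, with 3 arrays each. Errors are SDs over the 3 arrays of a passage for levels and standard errors (SE) for log2 changes, with n = 3 arrays per passage throughout.

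Between 38.6% and 47.8% of probes were above background on an array. The lowest share was on P2 replicate 1, and the other 8 arrays ranged from 43.5% upward. Correlations of log2 intensity across genes, which are not independent replicates, were 0.99 to 0.995 between arrays of the same passage and 0.967 to 0.988 between passages. The median SD of a gene over the 3 arrays was 0.13 at P2, 0.12 at P8 and 0.10 at P14 on the log2 scale. The first principal component held 53.9% of the variance and set P2 apart from both later passages. The second held 18.2% and set P14 apart from P2 and P8.

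**Figure D1:**
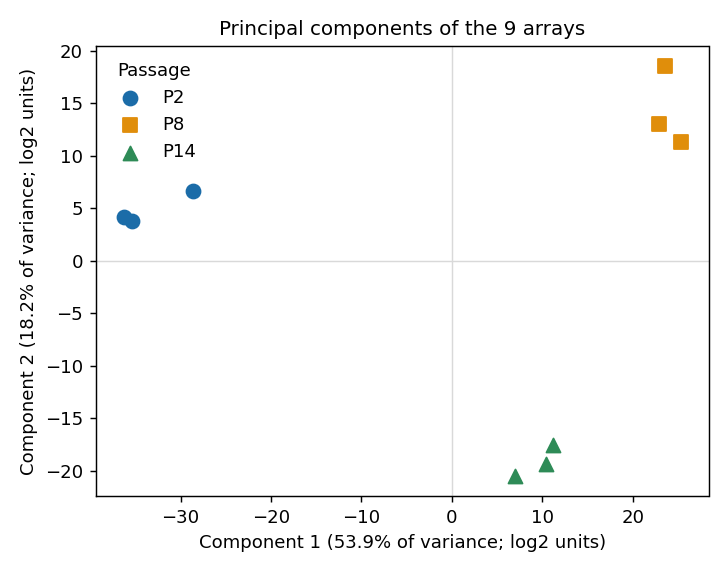
Each point is 1 array, placed by its scores on the first principal component (horizontal axis, 53.9% of variance) and the second (vertical axis, 18.2% of variance), both in log2 units. The P2 arrays lie between -36.3 and -28.6 on the first component, the P8 arrays between 22.9 and 25.3, and the P14 arrays between 7.01 and 11.2.

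P14 against P2 asked how the cells differed between the earliest and the latest passage. Genes of squamous differentiation and immediate early genes were lower at P14, while genes of the cell cycle and mesenchymal markers were higher. S100A7, an antimicrobial protein of squamous epithelium, went from 10.88 ± 0.15 to 5.48 ± 0.06 on the log2 scale, 42.3-fold lower. FOS, a transcription factor induced within minutes of a stimulus, went from 12.90 ± 0.06 to 8.47 ± 0.11, 21.5-fold lower. COL6A3, a chain of type VI collagen, went from 5.20 ± 0.24 to 8.31 ± 0.07, and at P2 it was above background on 1 of the 3 arrays. The keratin KRT5 and the transcription factor TP63, both markers of basal cells, did not pass the test: the changes were -0.05 ± 0.06 (adjusted p = 0.623, limma) and -0.12 ± 0.06 (adjusted p = 0.186, limma), and both turned positive with median scaling. The probes of TP63 differed in sign.

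In all, 4354 of 15728 genes (27.7%) passed in limma, 2505 higher and 1849 lower at P14. A change of at least 2-fold was estimated for 107 of the rises and 247 of the falls. The 3 arrays of P14 lay wholly above or below those of P2 for 6550 genes (41.6%), where chance gives 10%. The balance of rises and falls rested on the scaling of the arrays. Rises made up 57.5% of the passing genes, and 87.4% with median scaling, which moved the median change of all genes from 0.03 to 0.19 on the log2 scale. Changes are therefore given relative to the quantile-normalized median, and small ones can turn with it.

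Oncogenes and tumour suppressors are the groups that the design of the series names, and neither shifted as a list. Of 70 oncogenes tested, 11 rose and 16 fell, and adjusted over the list alone 31 passed, 13 of them rises. Their mean change was -0.11 and their median change 0.06, and the camera test, in the direction of a fall, gave an adjusted p = 0.335. The falls were led by FOS and by JUNB (-2.45 ± 0.10), JUN (-1.74 ± 0.09), the kinase PIM1 (-1.59 ± 0.10), MYC (-1.05 ± 0.07) and IDH2 (-0.84 ± 0.08). FOS, JUNB, JUN and MYC are also immediate early genes. The rises were led by ETV5 (1.16 ± 0.16), the mitotic kinase AURKA (1.10 ± 0.08), the lung transcription factor NKX2-1 (1.01 ± 0.11), HRAS (0.59 ± 0.09) and CCND3 (0.55 ± 0.07). PDGFRB, the PDGF receptor beta of mesenchymal cells, was below background on all P2 arrays and was at least 1.09-fold higher at P14. EGFR rose by 0.35 ± 0.08 on its brightest probe, but its probes differed in sign. TERT, the catalytic part of telomerase, stayed below the filter on background.

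Of 75 tumour suppressors tested, 17 rose and 9 fell, and adjusted over the list alone 26 passed, 17 of them rises. Their mean change was 0.02 and their median change 0.05, while the mean lay -0.00605 from that of the other genes, opposite in sign to the camera test, which was in the direction of a rise with an adjusted p = 0.692. The rises included the DNA repair genes BRCA1 (1.06 ± 0.11), MUTYH (0.80 ± 0.12), FANCD2 (0.75 ± 0.10) and MSH6 (0.73 ± 0.08), with IRF1 (0.75 ± 0.16) and RBL1 (0.66 ± 0.13). The falls included PRDM1, a repressor active in terminal differentiation (-2.70 ± 0.09), KLF6 (-1.46 ± 0.10), TNFAIP3 (-1.25 ± 0.12) and the CDK inhibitor CDKN2B (-1.23 ± 0.10). FBXW7 fell by 0.49 ± 0.08 on its brightest probe, while its probes differed in sign. The values of RB1 (-0.09 ± 0.12, adjusted p = 0.636), CDKN1A (-0.06 ± 0.06, adjusted p = 0.509) and CDKN2A (-0.35 ± 0.14, adjusted p = 0.0659) did not pass in limma, and those of RB1 and CDKN1A turned positive with median scaling. The probes of CDKN1A differed in sign.

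Squamous and cornified envelope genes, which build the tough outer layer of stratified epithelia, formed the list with the smallest camera p. Of 55 members, 45 fell and 0 rose (adjusted p = 5.64e-40, camera; adjusted p = 0.0264 with the estimated correlation). Besides S100A7, the falls included SERPINB3 (-4.25 ± 0.16), the protease KLK8 (-3.37 ± 0.09), SPRR2E (-3.29 ± 0.11) and IVL (-1.30 ± 0.12). KRT13, a keratin of squamous mucosa, had a change of 0.05 ± 0.07 (adjusted p = 0.656, limma), which turned negative with cyclic loess.

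Immediate early genes, switched on within minutes by growth factors or stress, fell in 27 of 31 cases and rose in 1 (adjusted p = 3.04e-32, camera; adjusted p = 0.0083 with the estimated correlation). The falls included FOSB (-4.35 ± 0.13), ATF3 (-3.69 ± 0.10) and DUSP1 (-3.49 ± 0.08). NF-kB inflammatory genes fell in 16 of 26 cases and rose in 4 (adjusted p = 7.43e-09, camera; adjusted p = 0.0083 with the estimated correlation). Of the senescence-associated and secreted inflammatory genes, 15 of 33 fell and 8 rose (adjusted p = 0.000576, camera; adjusted p = 0.0375 with the estimated correlation). The changes were -3.24 ± 0.08 for the chemokine CCL20, -3.24 ± 0.10 for CXCL8, -2.26 ± 0.11 for CXCL2, -2.21 ± 0.15 for the cytokine IL36G and -3.45 ± 0.08 for the growth factor HBEGF.

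Cell cycle genes were higher at P14. Of 61 G2/M phase genes 58 rose and 0 fell (adjusted p = 7.37e-30, camera; adjusted p = 0.0322 with the estimated correlation), and of 46 S phase genes 35 rose and 0 fell (adjusted p = 3.15e-18, camera; adjusted p = 0.0276 with the estimated correlation). CDCA3 rose by 1.27 ± 0.11, HMMR by 1.26 ± 0.09, BIRC5, a survivin that acts in mitosis, by 1.24 ± 0.12, PBK by 1.20 ± 0.10 and TOP2A by 0.95 ± 0.10. GINS2 and MCM7, parts of the replicative helicase, rose by 1.26 ± 0.09 and 1.20 ± 0.08, EXO1 by 1.10 ± 0.12 and CDT1 by 1.06 ± 0.10. MKI67 was dim, rose by 0.45 ± 0.16 with an adjusted p = 0.0482 in limma, and lost that call under several settings. DNA repair genes rose in 25 of 55 cases and fell in 1 (adjusted p = 9.44e-06, camera; adjusted p = 0.0897 with the estimated correlation), with BARD1 at 0.96 ± 0.19, FANCI at 0.95 ± 0.09 and XRCC3 at 0.93 ± 0.09. Replication-dependent histone genes moved the other way: 9 of 15 fell and 2 rose (adjusted p = 1.35e-07, camera; adjusted p = 0.0235 with the estimated correlation), H4C8 by -1.44 ± 0.11, H2BC4 by -1.17 ± 0.14, H2AC18 by -1.16 ± 0.07 and H1-2 by -1.05 ± 0.10.

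Mesenchymal and fibroblast markers rose in 12 of 17 tested cases and fell in 1, S100A4, named here after its values were seen (adjusted p = 7.20e-06, camera; adjusted p = 0.046 with the estimated correlation), and 13 more were below the filter. DCN, the proteoglycan decorin, was at least 4.72-fold higher at P14, and the collagen chain COL3A1 at least 2.04-fold. For a gene below background on all 3 arrays of a passage, the change is given only as a bound against the background limit. The median change of the list was 0.80, and 0.39 with the 8 members of this kind at their bound. VIM, an intermediate filament of mesenchymal and many cultured cells, rose by 1.76 ± 0.09. The call of this list was lost without any 1 of the P14 arrays, when the filter left 9, 8 and 9 of its members: these still shifted by 0.51, 0.63 and 0.61, with adjusted p of 0.177 without P14 replicate 1, 0.0789 without P14 replicate 2 and 0.0732 without P14 replicate 3. With the genes of the filter over all arrays kept, tried after seeing this, the 17 members shifted by 0.90, 0.94 and 0.99. The call then held (adjusted p at most 3.66e-05, camera). That filter had used the left-out array, and members such as DCN and COL3A1 passed it only through the P14 arrays, which favours a rise. The held call therefore cannot show that the rise stands without an array. Of the extracellular matrix genes, 11 of 35 rose and 3 fell (adjusted p = 0.28, camera), with FBN2 at 1.76 ± 0.10, FBLN1 at 1.01 ± 0.11, MATN2 at -1.08 ± 0.11 and THBS2 at least 1.47-fold higher at P14.

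Among markers of airway cell types, basal cell markers fell in 8 of 30 cases and rose in 3 (adjusted p = 0.0397, camera; adjusted p = 0.427 with the estimated correlation). The desmosomal cadherin DSG3 (-1.01 ± 0.09), the integrin ITGA6 (-0.55 ± 0.09) and KRT15 (-0.53 ± 0.06) fell, KRT14 rose by 0.55 ± 0.06, and NGFR had 0.29 ± 0.15 (adjusted p = 0.172, limma). Secretory and goblet cell markers fell in 7 of 22 cases and rose in 2 (adjusted p = 0.0143, camera; adjusted p = 0.0897 with the estimated correlation), with the protease inhibitor SLPI at -2.51 ± 0.09, CLCA4 at -1.69 ± 0.13, CLCA2 at -1.20 ± 0.06 and LCN2 at -1.14 ± 0.09. LCN2 is also in the NF-kB list, and these falls alone do not show a loss of secretory or goblet cells. The club cell protein SCGB1A1 (-0.44 ± 0.18, adjusted p = 0.0826) and the mucin MUC5AC (-0.05 ± 0.17, adjusted p = 0.869) did not pass in limma. Both were close to background, and SCGB1A1 was above it on 3 arrays at P2 and 1 at P14. Of the ciliated cell markers, 3 of 15 rose and 2 fell (adjusted p = 0.596, camera), with CCNO at 0.99 ± 0.09, CAPS at -0.45 ± 0.12 and the tubulins TUBA1A at 0.42 ± 0.05 and TUBB4B at 0.36 ± 0.08. FOXJ1, the regulator of motile cilia, was below the filter. Of 6 alveolar markers 3 rose and 0 fell (adjusted p = 0.0483, camera; adjusted p = 0.154 with the estimated correlation): NKX2-1, LAMP3 (0.46 ± 0.12) and CAV1 (0.26 ± 0.06), of which CAV1 is also made by basal cells. This call was lost under most alternatives. Airway transcription factors rose in 5 of 29 cases and fell in 9 (adjusted p = 0.203, camera), with KLF4 at -1.32 ± 0.08, ELF5 at -1.26 ± 0.11 and FOXA2 at 0.79 ± 0.11. SOX2 fell by 0.26 ± 0.09 and turned to 0.04 with median scaling.

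Signalling lists around the inhibitors in the medium did not pass. The camera test gave adjusted p = 0.447 for TGF-beta response genes (6 of 31 rose, 7 fell), 0.258 for BMP response genes (4 of 18 rose, 6 fell) and 0.692 for WNT targets (3 of 23 rose, 5 fell). It gave 0.361 for YAP/TAZ targets (6 of 24 rose, 6 fell) and 0.155 for Notch pathway genes (2 of 20 rose, 5 fell). CCN2, which responds to TGF-beta and to YAP, fell (-2.56 ± 0.10), as did BHLHE40 (-0.87 ± 0.07), GADD45B (-2.02 ± 0.10) and IGFBP3 (-1.28 ± 0.13). Among BMP and Notch genes the falls included HES1 (-0.93 ± 0.09), BMP7 (-0.74 ± 0.10), NRARP (-1.45 ± 0.09), HES4 (-0.68 ± 0.10) and HES2 (-0.51 ± 0.07), and DLX5 was at least 1.47-fold lower at P14. ID1, a direct target of BMP signalling, fell by 0.66 ± 0.07 on its brightest probe, while its probes differed in sign. Among WNT genes the antagonist DKK1 rose by 1.29 ± 0.07, the feedback gene AXIN2 fell by 0.65 ± 0.16, PORCN fell by 0.87 ± 0.10, and NKD2 was at least 1.19-fold higher at P14.

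Cholesterol biosynthesis genes rose in 13 of 24 cases and fell in 1 (adjusted p = 0.000414, camera; adjusted p = 0.0292 with the estimated correlation), with MVD at 0.78 ± 0.11, HSD17B7 at 0.74 ± 0.15 and SC5D at -0.73 ± 0.11. Glycolysis and hypoxia genes fell in 13 of 38 cases and rose in 5 (adjusted p = 0.0143, camera; adjusted p = 0.212 with the estimated correlation), with ANKRD37 at -2.48 ± 0.11, CA9 at -1.22 ± 0.11, EGLN3 at -0.73 ± 0.11 and SLC2A3 at 0.99 ± 0.15. Type I interferon response genes rose in 11 of 39 cases and fell in 7 (adjusted p = 0.0986, camera), with HERC5 at 2.38 ± 0.16, OASL at 1.83 ± 0.17, IFIT1 3.11-fold higher and IFIT2 at 1.47 ± 0.10. HERC5 and OASL were above background on 1 of 3 P2 arrays. The remaining large rises were NPTX1 (5.65-fold, above background on 1 of 3 P2 arrays), RPL22L1 (2.34 ± 0.20) and PNMA8A (1.91 ± 0.15), both likewise above background on 1 of 3 P2 arrays, the meiotic cohesin REC8 (1.86 ± 0.12), and the transcription factor TBX2 and the hormone STC1, at least 2.58-fold and 2.61-fold higher at P14. The largest, 3.86 ± 0.15, was on a probe assigned to the pseudogene GAPDHP61, whose source transcript is uncertain. The remaining large fall was ADH7, an alcohol dehydrogenase (-3.40 ± 0.14).

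**Figure D2:**
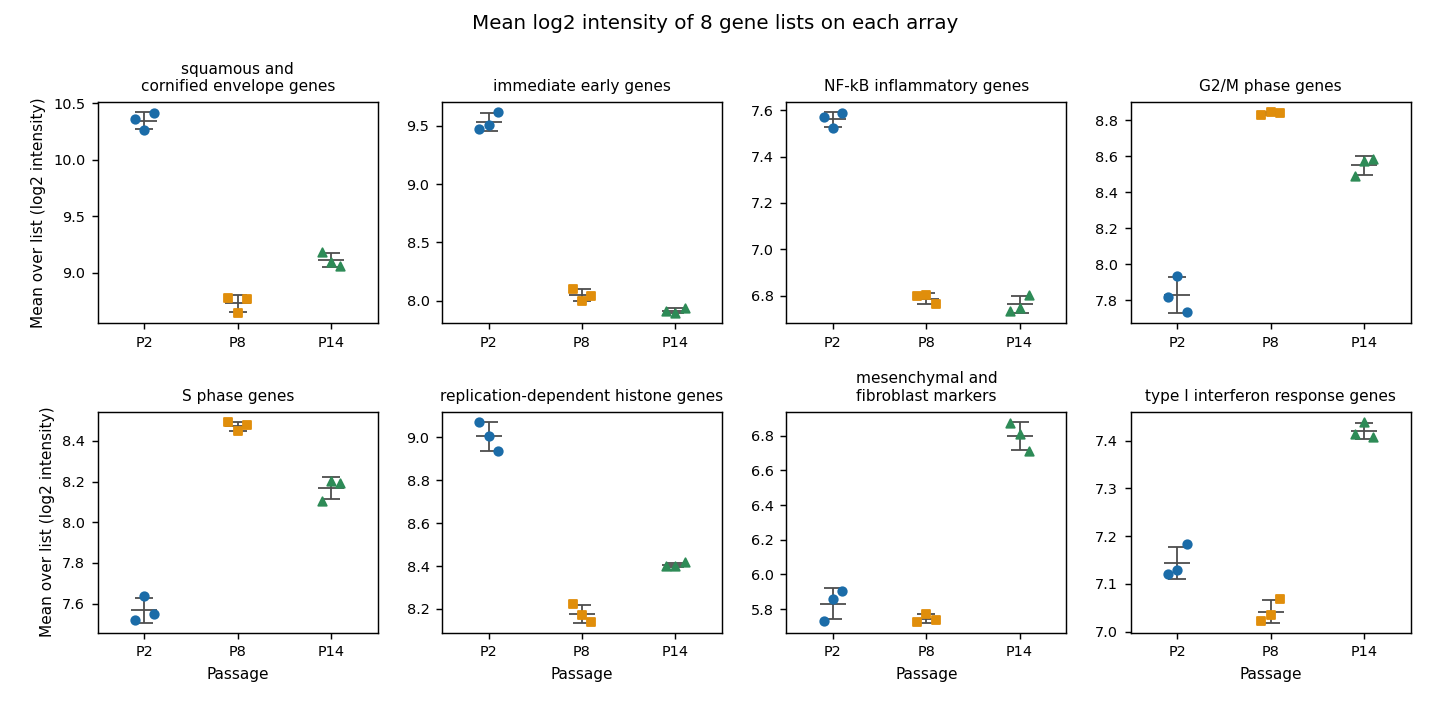
The mean log2 intensity over the tested members of each of 8 gene lists (vertical axes, each with its own range) is shown by passage (horizontal axes), with points for the arrays and bars for the mean and SD over 3 arrays. The squamous list mean went from 10.35 at P2 to 8.73 at P8 and 9.11 at P14, and the mesenchymal list mean from 5.83 to 5.75 and 6.80.

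P8 against P2 is the earlier of the equal steps of passages. Squamous and immediate early genes were already lower at P8, and cell cycle genes were already higher: the mean of the G2/M list was 7.83 ± 0.10 at P2, 8.84 ± 0.01 at P8 and 8.55 ± 0.05 at P14. S100A7 was 35.4-fold lower (-5.14 ± 0.13), followed by SERPINB3 (-4.96 ± 0.16), FOSB (-4.45 ± 0.13), FOS (-4.11 ± 0.08) and DAPL1 (-4.03 ± 0.13). The cytoskeletal regulator DPYSL3 was at least 4.05-fold higher at P8, and IL1RL1, a receptor for IL-33, was 3.73-fold higher. ETV5, NT5E (the surface enzyme CD73) and EPDR1 rose by 1.83 ± 0.16, 1.83 ± 0.13 and 1.81 ± 0.14.

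Of 55 squamous genes 49 fell and 2 rose from P2 to P8 (adjusted p = 6.73e-41, camera), of 31 immediate early genes 25 fell and 1 rose (adjusted p = 1.94e-20), of 26 NF-kB genes 16 fell and 2 rose (adjusted p = 1.70e-07), and of 15 histone genes 10 fell and 1 rose (adjusted p = 1.70e-07). Of 61 G2/M genes 57 rose and 0 fell (adjusted p = 1.84e-31), of 46 S phase genes 40 rose and 1 fell (adjusted p = 4.02e-22), and of 24 cholesterol genes 13 rose and 3 fell (adjusted p = 0.000617). These 7 lists kept an adjusted p of 0.0193 to 0.0281 with the estimated correlation. The others passed in camera with the preset correlation only, with adjusted p from 1.05e-06 to 0.0438. DNA repair genes rose in 30 of 55 cases and fell in 4, and senescence-associated genes fell in 13 of 33 and rose in 5 (adjusted p = 0.0823 for each with the estimated correlation). Airway transcription factors fell in 14 of 29 cases and rose in 5, and glycolysis and hypoxia genes fell in 15 of 38 and rose in 8 (adjusted p = 0.165 for each with the estimated correlation). Basal markers fell in 11 of 30 cases and rose in 3, and unfolded protein genes rose in 17 of 30 and fell in 7 (adjusted p = 0.261 for each with the estimated correlation). Notch genes fell in 7 of 20 cases and rose in 1 (adjusted p = 0.108 with the estimated correlation). Of the 17 mesenchymal markers 0 rose and 1 fell (adjusted p = 0.499, camera).

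In limma 5928 genes (37.7%) passed, 3286 higher and 2642 lower at P8. The arrays of P8 and P2 lay wholly apart for 7138 genes (45.4%), where chance gives 10%. Rises made up 55.4% of the passing genes and 79.2% with median scaling, which moved the median change of all genes to 0.15.

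P14 against P8 is the later step. Mesenchymal markers rose in 12 of 17 cases and 0 fell (adjusted p = 2.86e-11, camera; adjusted p = 0.0492 with the estimated correlation). Their median change was 1.00 as fitted, and 0.47 with the 10 members that were below background on all P8 arrays at their bound. Members such as DCN and COL3A1 passed the filter only through the P14 arrays, so the filter itself favoured a rise in this list. COL6A3 was at least 7.84-fold higher at P14, DCN at least 5-fold and NPTX1, a secreted pentraxin of neurons, at least 4.38-fold. The squamous keratin KRT4 rose by 2.41 ± 0.14, and the pseudogene probe of GAPDHP61 rose by 3.78 ± 0.15. DPYSL4 and the inflammasome gene NLRP2 were at least 5.48-fold and 3.27-fold lower at P14, while DPYSL3 (-1.89 ± 0.12), SLF1 (-1.88 ± 0.11) and EPDR1 (-1.81 ± 0.14) fell.

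Interferon response genes rose in 16 of 39 cases and fell in 3 (adjusted p = 1.22e-05, camera; adjusted p = 0.0492 with the estimated correlation). The other lists passed with the preset correlation only, with adjusted p from 5.79e-13 to 0.0343 in camera. Squamous genes rose in 34 of 55 cases and fell in 7 (adjusted p = 2.68e-12, camera; adjusted p = 0.156 with the estimated correlation). G2/M genes fell in 24 of 61 cases and rose in 1, and S phase genes fell in 23 of 46 and 0 rose (adjusted p = 0.156 and 0.0813 with the estimated correlation). Airway transcription factors rose in 13 of 29 cases and 0 fell, extracellular matrix genes rose in 15 of 35 and fell in 1, and histone genes rose in 7 of 15 and fell in 1 (adjusted p = 0.129, 0.0813 and 0.0813 with the estimated correlation). DNA repair genes fell in 9 of 55 cases and rose in 2, immediate early genes fell in 9 of 31 and rose in 2, and alveolar markers rose in 2 of 6 and 0 fell (adjusted p = 0.306, 0.334 and 0.156 with the estimated correlation).

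In limma 2617 genes (16.6%) passed, 1337 higher and 1280 lower at P14. The arrays lay wholly apart for 5266 genes (33.5%), where chance gives 10%. Without P14 replicate 1 the count was 1552. Rises made up 51.1% of the passing genes, 60.1% with median scaling and 36.0% with the deposited values on the log2 scale.

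The change from P8 to P14 minus the change from P2 to P8 asked whether the later step went on with the earlier one. Many genes turned back. KRT4, DAPL1, the melanosomal and lysosomal glycoprotein GPNMB, SERPINB3 and the cornified envelope protein RPTN had the largest fitted positive differences, and DPYSL3, EPDR1, DPYSL4, NT5E and ETV5 the largest fitted negative ones. KRT4 went from 11.71 ± 0.19 to 7.81 ± 0.32 and 10.22 ± 0.24 at P2, P8 and P14, a difference between steps of 6.31 ± 0.24 on the log2 scale. DPYSL3 went from 4.86 ± 0.10 to 7.43 ± 0.08 and 5.54 ± 0.004, with all P2 arrays below background, so the difference is -3.91 or lower. KRT14, a basal keratin, went from 12.53 ± 0.05 to 10.82 ± 0.03 and 13.08 ± 0.11.

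The difference passed for 4865 genes in limma, 2290 positive and 2575 negative. Positive differences made up 47.1% of these, 30.3% with median scaling and 38.8% with the deposited values on the log2 scale. Median scaling put the median difference of all genes at -0.14. Of genes that passed in both steps, 957 rose and then fell, 921 fell and then rose, 51 rose in both and 72 fell in both. Independent lists of the same sizes would give 267, 225, 279 and 215. Squamous genes had 48 positive and 1 negative differences among 55, immediate early genes 20 and 1 among 31, NF-kB genes 11 and 0 among 26, histone genes 10 and 1 among 15, and interferon genes 20 and 5 among 39. G2/M genes had 0 positive and 57 negative differences among 61, S phase genes 1 and 38 among 46, and cholesterol genes 2 and 11 among 24. These 8 lists passed in camera with both correlations, with adjusted p from 0.0295 to 0.0463 with the estimated one. For mesenchymal markers the difference was positive for 11 of 17 and negative for 0 (adjusted p = 1.36e-05, camera; adjusted p = 0.0517 with the estimated correlation). Some of these markers passed the filter only through the P14 arrays, which favours a positive difference. The differences of 8 further lists (airway transcription factors, basal, TGF-beta response, Notch, glycolysis and hypoxia, DNA repair, extracellular matrix and unfolded protein genes) passed with the preset correlation only, with adjusted p from 0.0756 to 0.289 with the estimated one. A positive difference does not require a rise in the later step: from P8 to P14, 9 immediate early genes fell and 2 rose, and 4 NF-kB genes fell and 3 rose. The P8 arrays enter both steps with opposite signs.

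**Figure D3:**
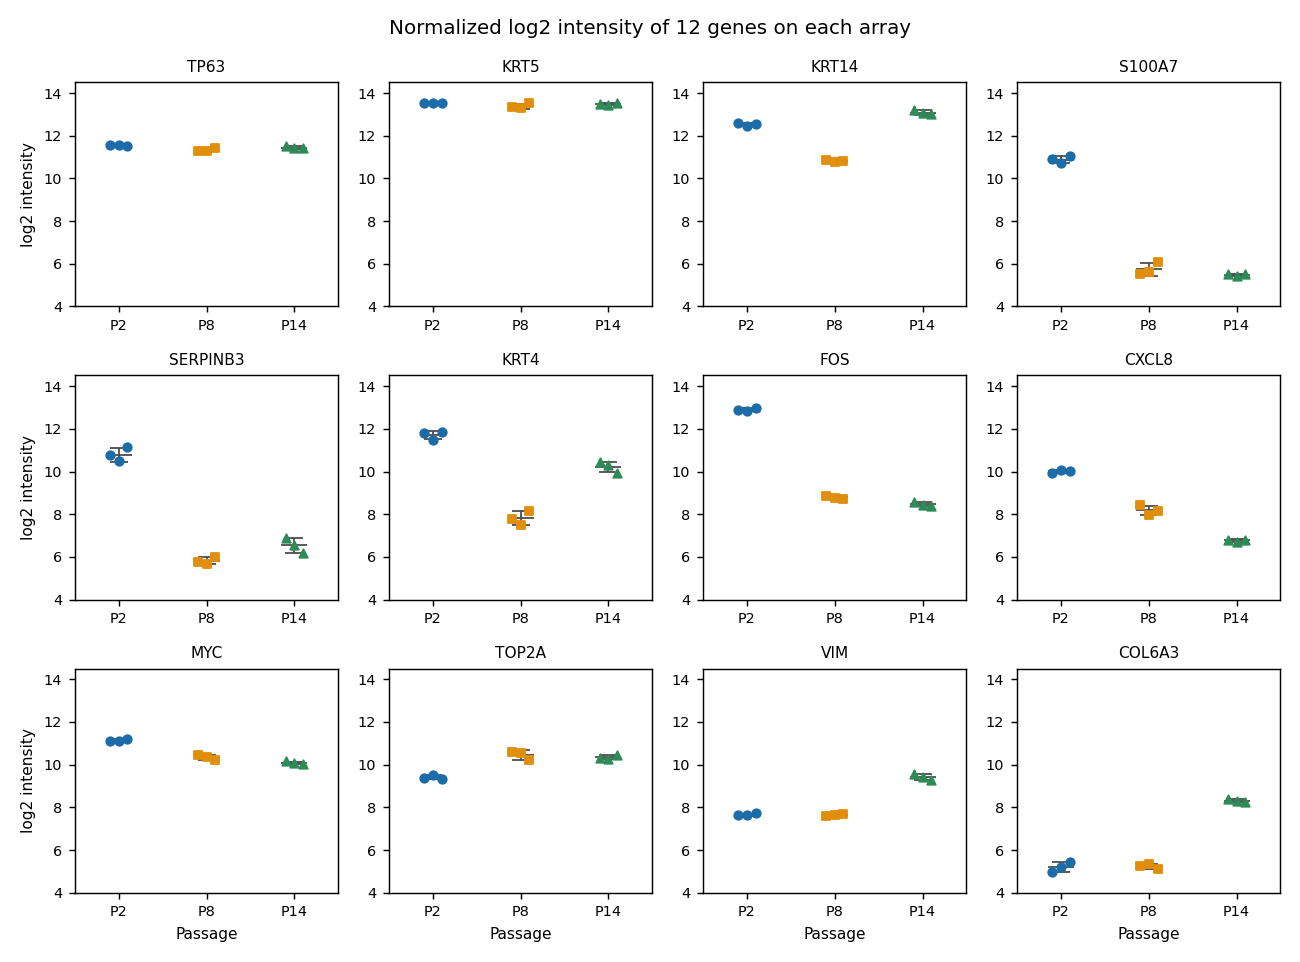
Normalized log2 intensity (vertical axes) of 12 genes is shown by passage (horizontal axes), with points for the arrays and bars for the mean and SD over 3 arrays. FOS lay at 12.90, 8.79 and 8.47 at P2, P8 and P14, VIM at 7.66, 7.64 and 9.42, and KRT5 at 13.53, 13.38 and 13.48.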

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

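The tests of the scaling of the arrays, of shared P8 arrays, of the filter kept, of a loss of squamous cells and of handling at harvest were chosen after the results were seen, while those of fibroblast genes and of other splits were set before.

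The change from P8 to P14 differed from the change from P2 to P8, by a test of the difference itself, for 4865 genes in limma and for 17 of the 34 lists in camera with the preset correlation. With the estimated correlation 8 of these lists passed: squamous, immediate early, histone, NF-kB, interferon, G2/M, S phase and cholesterol genes. The others did not, among them mesenchymal genes with an adjusted p = 0.0517. As log2 differences of each list's mean against the other genes, the 17 were 2.01 for squamous, 1.36 for immediate early, 1.14 for mesenchymal, 1.06 for histone, 0.75 for NF-kB, 0.61 for airway transcription factors, 0.48 for interferon, 0.42 for extracellular matrix, 0.41 for basal, 0.39 for TGF-beta response, 0.38 for glycolysis and hypoxia and 0.34 for Notch genes. They were -1.30 for G2/M, -1.21 for S phase, -0.52 for DNA repair, -0.37 for cholesterol and -0.0678 for unfolded protein genes. Among named genes the differences were 6.31 for KRT4, 5.88 for DAPL1, 5.67 for SERPINB3, 5.44 for RPTN, -3.62 for EPDR1, -3.06 for NT5E and -2.50 for ETV5. For genes below background on all arrays of a passage they were at least 5.56 for GPNMB, below background at P8, -3.91 or lower for DPYSL3, below it at P2, and -2.63 or lower for DPYSL4, below it at P14.

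Other splits of the arrays were run for each comparison. For the pairwise comparisons only 10 splits of 6 arrays exist, which are too few for a share under 0.05. The real numbers of genes were 4354, 5928 and 2617 for P14 against P2, P8 against P2 and P14 against P8, and the highest of the other splits was 0 in each, with limma at the adjusted threshold. The real numbers of lists were 14, 14 and 11 and the highest others 8, 9 and 9 with the preset correlation. With the estimated correlation the real numbers were 9, 7 and 2 and the highest other 0 in each. Every other split still sets 2 arrays of a passage against 1, so it keeps part of the difference between passages. It also puts that difference into the spread within a group, so 0 genes are likely wherever the passages differ. The gap between the real numbers and 0 therefore does not measure the strength of the result. For the difference between steps 100 splits were drawn. Of the 100, 1, the real one, reached 4865 genes (highest other 1103) and 17 lists (highest other 13). A random order of the 9 arrays thus seldom gave as many calls. Mixing of passages lowers the counts of the drawn splits too, so the gap to 1103 does not measure strength either. Chance differences between cultures are not covered, since the arrays of a passage may be technical repeats and the other splits mix passages.

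Of the genes that passed in both steps, 1878 moved in opposite directions. Chance values of the P8 arrays, which both steps share, are argued against as the whole cause: with separate P8 arrays for each step, 1 in one and 2 in the other, from 78.6% to 94.3% of the genes that passed in both moved in opposite directions over 6 assignments, the lone array being assumed to vary like the others. The scaling of the arrays is argued against as the whole cause for the squamous and G2/M lists only. Over 4 scalings their difference between steps nearest 0 was -1.02 and kept its sign and its call. These lists were picked after the results were seen, and a shift against the other genes cannot show a constant offset of an array. The 1878 genes were not counted again under these scalings. With median scaling, 81.7% of the 4865 genes with a difference between steps passed again in the same direction, and 1 passed in the opposite one. Shared P8 arrays may still add to the number of genes with real changes, and a state of the P8 harvest cannot be separated from passage. The biological explanation that the design gives, the number of passages, stays open and untested.

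The fitted mean change of mesenchymal and fibroblast markers from P2 to P14 exceeded that of the other genes by 0.95 on the log2 scale, but 8 of the 17 members were below background on all P2 arrays, their median change was 0.39 with these at their bound against 0.80 as fitted, and the call was lost without any 1 P14 array (adjusted p = 0.177, 0.0789 and 0.0732 in camera without P14 replicate 1, without P14 replicate 2 and without P14 replicate 3). The filter of at least 3 arrays then dropped members seen only at P14, such as DCN, and left 9, 8 and 9 members with shifts of 0.51, 0.63 and 0.61. With the genes of the filter over all arrays kept the shifts were 0.90, 0.94 and 0.99 and the call held. That filter had used the left-out array and had admitted such members through the P14 arrays, which favours a rise. The held call therefore cannot show that the rise stands without an array. The mean of the same 17 members was 6.88, 6.81 and 6.71 on the P14 arrays against 5.73 to 5.91 on the others. The scaling of the arrays is argued against, since the smallest shift over 4 scalings was 0.41 and passed. RNA from fibroblasts or related cells in the P14 cultures may contribute. Of 24 further fibroblast genes, listed before their values were seen, 16 were above the filter. Of these, 5 (31.2%) rose from P2 to P14 and 4 (25%) from P8 to P14, while 0 fell in either. Over all 15728 genes 2505 and 1337 rose. The 31.2% and 25% passed neither limit set before, for or against this explanation, so it stays undecided. From P2 to P8 1 of the 16 rose and 4 fell. FSTL1, PCOLCE, PRRX1, NNMT and LAMA4 rose from P2 to P14, and of these only PCOLCE and PRRX1 also rose from P8 to P14. MFAP5 and CALD1 rose from P8 to P14 after a fall from P2 to P8. COL1A1, abundant in fibroblasts and chosen here after its values were seen, went from 5.69 to 6.39. A few such cells and a change within the epithelial cells cannot be told apart with bulk RNA. Passage number itself stays open and untested.

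Immediate early genes were higher at P2, and their list mean fell by 1.62 on the log2 scale to P14. The scaling of the arrays is argued against, since the shift nearest 0 over 4 scalings was -1.30. Fewer squamous cells after P2 stay open: squamous genes regained 23.6% of their fall from P8 to P14 which would give a rise of 0.35 in immediate early genes, and the observed change of -0.13 with an SE of 0.03 goes against that, but the regain had an adjusted p = 0.156 in camera with the estimated correlation, and the immediate early RNA of squamous cells was not measured. Handling at harvest could raise these genes on every P2 array alike, and the SD of the list mean over the P2 arrays was 0.0762. It cannot be told apart from passage number, since each passage has its own harvest.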

How the results depend on the processing

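The count of list members without P2 replicate 1, the array with the fewest probes above background, and the mesenchymal list without each P14 array with the genes of the filter over all arrays kept were added after seeing the data, and the other alternatives were planned. The second raw table and a term for the slide were not run, since their columns match no label. Replicate numbers were checked as pairs: after passage means were removed, 0 of 9 pairs with equal numbers correlated above 0.1 (r from -0.06 to 0.07, across genes), so the numbers do not pair the arrays. With replicate number as a block 4347, 5960, 2660 and 4870 genes passed for P14 against P2, P8 against P2, P14 against P8 and the difference between steps.

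Over the other settings the counts ran from 3858 to 5941, 5425 to 6550, 1852 to 3472 and 4403 to 5399, all within 1.5 times the values reported. Without each array in turn they ran from 3434 to 4865, 5238 to 5879, 1552 to 2755 and 4044 to 4818, and the 1552 was without P14 replicate 1. Of the gene values under other settings 2080 kept direction and call, 35 lost the call, 6 gained it and 8 reversed, and without single arrays 1582, 18, 2 and 3 did. Of the list values under other settings 641 kept both, 28 lost the call and 5 reversed, and without single arrays 502, 23 and 3 did. The 14 lists that passed for P14 against P2 kept the direction of their member counts without P2 replicate 1.

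The shift of tumour suppressors, P14 against P2, was -0.00605 as reported, 0.021 with median scaling, 0.0222 without a filter, 0.0123 with the mean over probes, 0.0124 with the deposited values, and -0.0111 to 0.00785 without single arrays, and it passed in none. With median scaling TP63 was 0.15, KRT5 0.11, CDKN1A 0.15, RB1 0.14 and SOX2 0.0364. CDKN1A was 0.0718 with the mean over probes, KRT13 -0.0233 with cyclic loess and POU2F3 -0.10 with the deposited values. Without single arrays MUC5AC ran from -0.13 to 0.0789 and POU2F3 from -0.049 to 0.19. The shift of unfolded protein genes for P8 against P2 was -0.00157 with the stricter filter. MKI67 ran from 0.33 to 0.62 without single arrays, with adjusted p from 0.0114 to 0.519 over all settings in limma. The loss of the mesenchymal call without single P14 arrays came with fewer members above the filter. With the genes of the filter over all arrays kept the shift of the list ran from 0.90 to 0.99 and passed. That filter had used the left-out array, so the pass does not show that the call stands without it. The cause of the other changes was not tested. Signal over background limits the dim genes, among them 13 of the 30 mesenchymal markers and 20 of the 90 oncogenes on the array.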

Other observations

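No test in this part was chosen after the results were seen, and the lists were fixed before the data were examined.

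Genes of xenobiotic metabolism went both ways between P2 and P14. Of 37 NRF2 and xenobiotic genes 8 rose and 11 fell (adjusted p = 0.207, camera), with the cytochromes CYP1A1 at -1.86 ± 0.12 and CYP4F3 at -1.20 ± 0.11, the reductase AKR1B10 at -1.35 ± 0.07 and the glucuronosyltransferase UGT1A6 at -1.11 ± 0.08. Unfolded protein and heat shock genes rose in 16 of 30 cases and fell in 8 (adjusted p = 0.155, camera), with ASNS at 1.05 ± 0.10, CRYAB at -1.02 ± 0.10 and HERPUD1 1.99-fold lower. Of 17 telomere genes 4 rose and 2 fell (adjusted p = 0.949, camera), with STN1 at -0.99 ± 0.07, ACD at 0.51 ± 0.11, GAR1 at 0.43 ± 0.09 and WRAP53 at 0.46 ± 0.15.

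Of 49 oxidative phosphorylation genes 10 rose and 7 fell (adjusted p = 0.949, camera), with NDUFS8 at 0.40 ± 0.08, NDUFA10 at 0.39 ± 0.11, CYCS at -0.41 ± 0.10 and SDHC at -0.38 ± 0.08. Of 71 cytosolic ribosomal protein genes 4 rose and 5 fell (adjusted p = 0.591, camera), with RPS23 at -1.94 ± 0.08, RPL28 at -0.49 ± 0.11, RPS7 at 0.40 ± 0.07 and RPS26 at 0.33 ± 0.06. Few markers of other cell types were above the filter. Of 6 immune markers 1 rose and 1 fell (adjusted p = 0.361, camera), CD14 with 0.44 ± 0.09 and CD74 with -0.62 ± 0.14. Of 5 endothelial markers 1 rose and 1 fell (adjusted p = 0.848, camera), with VWF at -0.91 ± 0.11 and ENG at least 1.2-fold higher at P14. Of 6 neuroendocrine and ionocyte markers 0 rose and 0 fell (adjusted p = 0.761, camera), with UCHL1 at -0.28 ± 0.19 and POU2F3 at 0.10 ± 0.18. The median, mean and test of a list differed in sign for P14 against P2 for several lists, among them oncogenes, TGF-beta response, YAP/TAZ, NRF2, unfolded protein, WNT, telomere, endothelial and oxidative phosphorylation genes, of which none passed in camera.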
